A study of Mus musculus with 1087 samples.

How the data were processed

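Messenger RNA was sequenced in single cells from the aorta-gonad-mesonephros (AGM) region of mouse embryos, where the first hematopoietic stem cells form in clusters on the wall of the aorta. Per the labels, the embryos carried 1 allele of a Gata2 gene linked to the Venus fluorescent protein, tissue was dissociated with collagenase, and live cells were sorted with antibodies against CD31, cKit and CD27 and on Venus fluorescence. The sample names call every cell high for Kit. They give the day (E10, E11 or E11.5) and the gate, which is G2VInt (intermediate Venus), G2VLo (low Venus) or CD27+. The Venus level of the CD27+ cells is not stated. Each of the 1087 samples is 1 cell.

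The deposited table holds raw read counts per Ensembl gene, and the unit is counts. Per the submitters' processing notes, HTSeq 0.6.0 and the GRCm38 genome were used; the aligner, the annotation release, the strand setting and the read filters are not stated. Libraries were made with Nextera XT and read on an Illumina HiSeq, per the labels. No molecular identifiers are mentioned, so copies made by PCR were counted as reads. All 1087 columns held whole numbers, no spike-in or summary entries were found (0), and no pair of cells had identical columns (0). Of 46078 genes, 45143 were matched to a symbol of GENCODE M21, whose coordinates are on the same build, and the 935 without a match held 0.0960% of the counts. The labels also give each cell's cluster in the authors' clustering of all cells, and, for all cells but the CD27+ ones, a cluster of a second clustering and a class (EC, HC1, HC2, U1 or U2). These assignments were taken as given. EC and HC were read as endothelial and hematopoietic from marker genes; the labels do not spell them out.

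The labels name no embryo, litter or sort, so each of the 5 groups is 1 sample and its cells are not replicates. No test was run, no p-value is given and no number of changed genes was counted. For each comparison the counts of a group were summed over its cells and expressed as CPM, which scales each group to the same total, with exact Poisson 95% intervals. Shares of cells carry exact Clopper-Pearson 95% intervals. Both cover counting error only, not differences between embryos, sorts or library blocks, and PCR copies make them too narrow. A count of 0 allows a value of up to 3 counts of the total. Where the share of cells with a read of a gene is given, each cell was first thinned at random to 100000 reads, a depth that all 1087 cells reached. Library numbers in the sample names fall into blocks that do not mix groups. Those of E10 and E11 are adjacent, and that of the E11.5 G2VInt cells lies apart. The block of the CD27+ cells (19694 to 19812) lies inside the range of the E11.5 G2VLo cells (19310 to 19908) without sharing numbers with it. G2VLo cells therefore lie on both sides of the CD27+ block. The labels name no run.

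There were 6 comparisons of all cells and 9 within a class or cluster. The EC class was compared by its clusters 1 and 2, because the leading genes of cluster 1 held more markers of another tissue (Gata4) than of endothelium; the rule for this was fixed in advance and was applied once these genes were known. The comparisons within hematopoietic cells used the authors' classes HC1 and HC2 and, for CD27+ cells, cluster 8 of the clustering of all cells, which holds most of them. Genes used to form such clusters are not independent of them.

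The genes named were chosen by a rule fixed before the data were examined. It takes Gata2, Kit, Cd27 and Pecam1 (the reporter gene and the sorted proteins), and the 10 highest and 10 lowest ratios of each comparison of all cells (5 and 5 within a class). Such a gene had at least 10 CPM in 1 group, a read in at least 20% of the thinned cells of the higher group, at least a 2-fold ratio, and at least a 1.5-fold ratio in the same direction for the mean of per-cell CPM and with either group reduced to its lower or upper library numbers. Pseudogenes, unnamed genes, mitochondrial and ribosomal protein genes were passed over, as were the sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. Other genes of the X chromosome were kept, although the share of male cells differed between groups. The rule also takes the 2 to 4 members with the largest ratio of each of 28 gene lists (459 entries, of which 457 were in the table), which were written from textbook knowledge before the data were examined. Some genes are in more than 1 list, so the lists are not independent of each other. A few genes that met the rule are not named. Other genes named in passing, and those in single clusters, were chosen after their values were seen.

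A list was described by the median log2 ratio of its members with at least 10 CPM in 1 group and a read in at least 5% of its cells, given relative to the median of all genes that met the same limits, and by its percentile among 10000 random lists of as many genes matched on expression in 20 levels. Percentiles place a list among the genes of these libraries and are not p-values. Counts of members that were positive, negative or at least 2-fold apart use plain ratios, not relative ones. The use of relative medians, and a limit of 1.5-fold for calling a ratio or median moved by an alternative, were set after list values had been seen. The rules were tested on simulated counts, drawn for each gene and cell from a model with the means and spread of real cells. Altered genes had at least 20 CPM, and no difference between embryos, library blocks or classes was built in. With the cell numbers and depths of the E11.5 G2VInt and G2VLo groups, genes set at 3-fold passed the named-gene rule in 100% of 50 cases, genes at 2-fold in 50%, and 12 of 9837 unaltered genes (0.122%) passed. With those of the small comparison of CD27+ and G2VInt cells in cluster 8, 84% of 50 genes at 3-fold and 450 of 9573 unaltered genes (4.70%) passed, so single genes of that comparison are uncertain.

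Alternatives were the mean of per-cell CPM, TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors, no CPM filter, cells of at least 100000 counts, leaving out the deepest 5% of cells, the lower or the upper library numbers of each group alone, and leaving out classes U1 and U2. CD27+ cells have no class, so those of clusters 3, 5 and 6 of the clustering of all cells were left out instead. The 9 CD27+ cells of cluster 4, which held 16 EC, 4 HC1, 1 U1 and 11 U2 cells, were kept. For shares the alternatives were the clustering of all cells, no thinning, thinning to 50000 reads and at least 5 reads. A minimum of 300000 counts was added after it was seen that 100000 removed no cell, and the HC1 cells of cluster 7 or 8 alone after the HC1 values were seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. Cells were not clustered again and no pseudotime was computed. No cell was left out.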

Results

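Single-cell transcriptomes were measured in cells labeled Kit-high and sorted from the AGM region of embryos that carry a Venus reporter of Gata2, a transcription factor needed to make and keep hematopoietic stem cells (HSCs). Intra-aortic hematopoietic clusters bud from the endothelium of the aorta at these stages and hold the first HSCs. The cells fell into 5 groups. G2VInt cells, with intermediate Venus, were sampled on 3 days: 87 at E10, 130 at E11 and 279 at E11.5. At E11.5 there were also 472 G2VLo cells, with low Venus, and 119 cells sorted as CD27+. CD27 is a surface receptor of the TNF receptor family found on early HSCs and lymphocytes.

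All cells together held 1380367268 reads on genes, from 117369 to 6999570 per cell with a median of 818924. Median depth differed between groups: 2121423 reads per cell at E10, 2212898 at E11 and 1892779 at E11.5 in G2VInt cells, 539090 in G2VLo cells and 621544 in CD27+ cells. The median number of genes with a read was 11085, 10814, 11109, 8695 and 9188 in that order. Mitochondrial genes took a median of 2.04% of the reads of E10 cells, 2.62% at E11 and 2.93% at E11.5, against 6.41% in G2VLo and 8.29% in CD27+ cells. Each group is a single sample without replicates, so the values below describe these libraries, and differences between groups were not tested.

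The labels sort all cells but the CD27+ ones into 5 classes, and the shares of these classes describe the make-up of each group. EC cells were rich in Pecam1, which encodes the endothelial protein CD31 (958 CPM at E11.5 in G2VInt cells, against 425 in HC1 and 89.1 in HC2). HC1 cells, the class with HSC genes, made up 72.4% of the E10 cells (95% interval 61.8 to 81.5), 59.2% at E11 (50.3 to 67.8) and 36.6% at E11.5 (30.9 to 42.5) within G2VInt. EC cells made up 16.1% at E10 (9.09 to 25.5), 11.54% at E11 (6.60 to 18.3) and 43.7% at E11.5 (37.8 to 49.8). Leading genes of the HC2 clusters include those of myeloid cells (Mpo), mast cells (Cpa3) and erythroid cells (Ermap). HC2 cells made up 9.20% (4.05 to 17.3), 27.7% (20.2 to 36.2) and 15.8% (11.7 to 20.6) on these days.

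At E11.5, EC and HC1 were the largest classes in both Venus gates, and the gates differed in U1, a class of cells with macrophage genes. EC cells were 39.0% of G2VLo (34.6 to 43.6) and HC1 cells 34.5% (30.3 to 39.0), with intervals that overlap those of G2VInt. The make-up of EC differed, however. EC cluster 1 was 24.4% of G2VInt (19.45 to 29.85) and 12.7% of G2VLo (9.84 to 16.1). EC cluster 2 was 19.35% (14.89 to 24.49) and 26.3% (22.35 to 30.49). HC2 cells were 7.63% of G2VLo (5.40 to 10.4), or 4.03% by the clustering of all cells, below the 15.8% of G2VInt. U1 cells were 16.3% of G2VLo (13.1 to 19.96) and 2.87% of G2VInt (1.25 to 5.57). No U1 cell was found at E10 (0 of 87, which allows a share of up to 3.45%) or E11 (0 of 130, which allows up to 2.31%). Most CD27+ cells lay in hematopoietic clusters: by the clustering of all cells, 78.2% were in clusters made mostly of HC1 cells (69.7 to 85.2), against 38.6% of G2VLo (34.2 to 43.1) and 36.6% of G2VInt, and 58.0% were in cluster 8 alone (48.6 to 67.0). No CD27+ cell lay in a cluster made mostly of HC2 cells (0 of 119, which allows up to 2.52%). Cluster 8 also held 29 HC2 cells, so this does not show that CD27+ cells lacked cells like HC2. The shares of G2VLo differed between the lower and the upper library numbers for EC (48.3% and 29.7%) and HC1 (25.4% and 43.6%), as did that of HC1 in G2VInt at E11.5 (29.3% and 43.9%), so they also varied within a group.

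**Figure D1:**
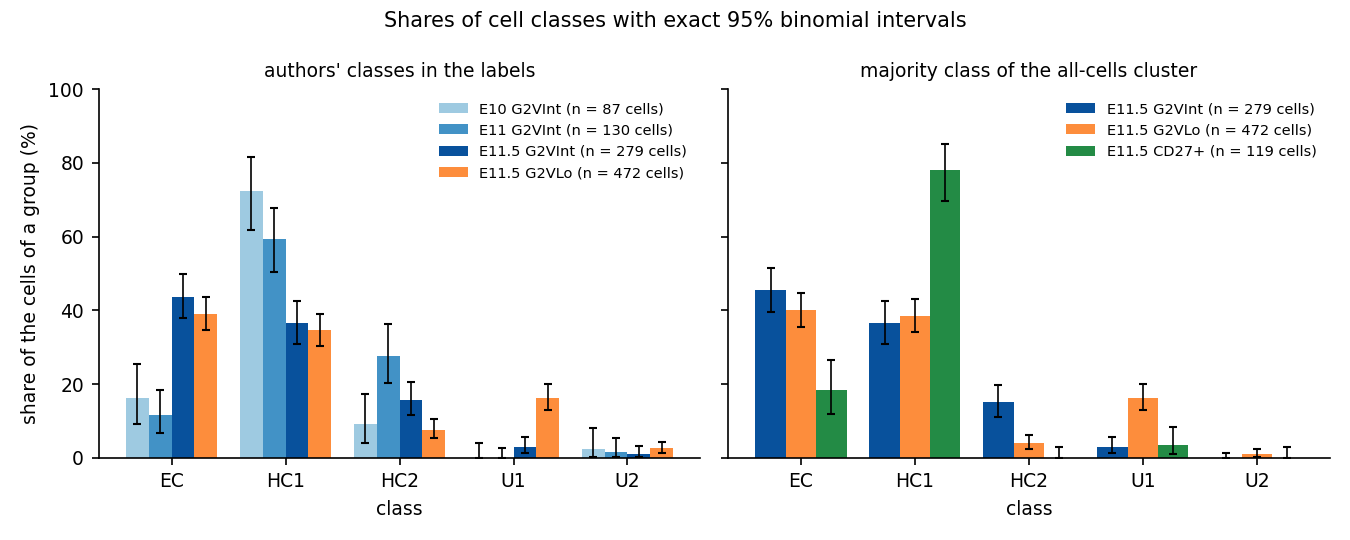
Shares of cells (y axis, percent of the cells of a group) in each class (x axis), on the left by the classes in the labels and on the right by the main class of each cluster of all cells; bars are groups and lines are exact 95% binomial intervals. HC1 is 72.4% of G2VInt cells at E10 and 36.6% at E11.5, U1 is 16.3% of G2VLo cells, and 78.2% of CD27+ cells are in HC1 clusters.

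The first comparison asks what separates intermediate from low Gata2 reporter at E11.5. Gata2 itself (ENSMUSG00000015053, chromosome 6, 88193891 to 88207032, plus strand, GRCm38) followed the gate: 168 CPM in G2VInt (167 to 169) and 67.0 in G2VLo (66.0 to 68.0), a ratio of 2.51. A read of Gata2 was seen in 91.8% of G2VInt cells (87.9 to 94.7) and 66.5% of G2VLo cells (62.1 to 70.8) at equal depth. The gap was present inside the classes, with 244 against 125 CPM in HC1 and 358 against 141 in HC2, and with 102 against 58.7 in EC cluster 1 and 55.3 against 34.7 in EC cluster 2. Transcripts of the sorted proteins differed less. Kit, the stem cell factor receptor (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, plus strand), had 342 and 252 CPM. Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628, minus strand) had 642 and 498, and Cd27 (ENSMUSG00000030336, chromosome 6, 125232622 to 125237010, minus strand) 36.7 and 28.0.

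**Figure D2:**
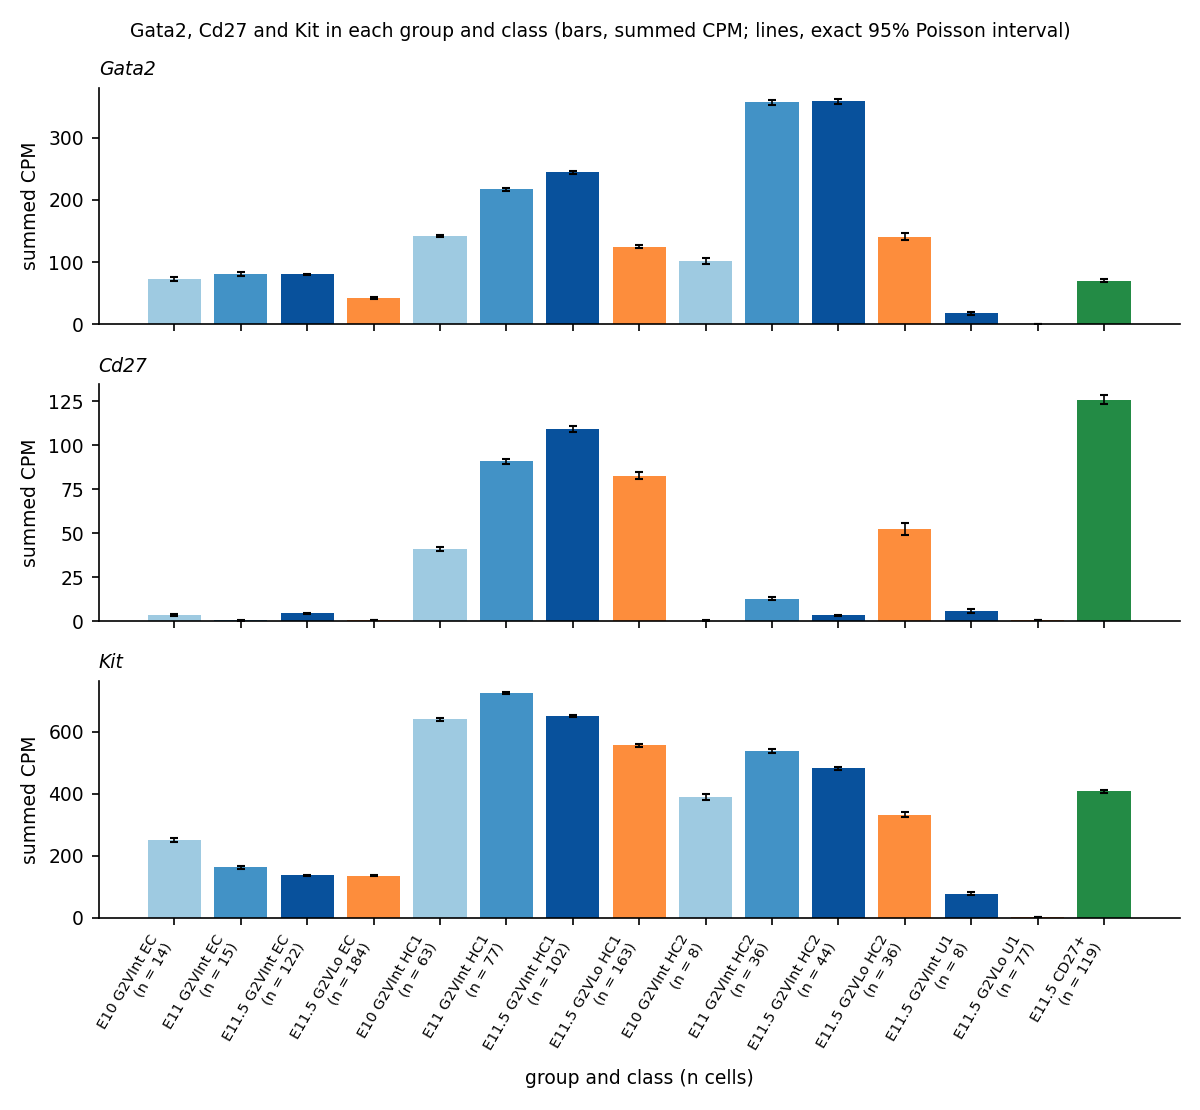
Summed CPM (y axis) of Gata2, Cd27 and Kit in each group and class (x axis, with the number of cells); bars are CPM and lines exact 95% Poisson intervals. Gata2 is higher in G2VInt than in G2VLo cells of each class, Cd27 is 126 CPM in CD27+ cells, and U1 cells of G2VLo have 1.72 CPM of Kit.

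Macrophage genes were lower in G2VInt cells. The 10 lowest named genes were Cd83, Mrc1, C3ar1, Ctss, Cx3cr1, Fcgr1, Itgb5, Ms4a6b, Rassf4 and Cd33, and 10 of 11 measured members of the macrophage list were at least 2-fold lower (median relative log2 ratio -2.22, percentile 0 among random lists). Mrc1, the mannose receptor, had 29.3 CPM in G2VInt and 192 in G2VLo. The fractalkine receptor Cx3cr1 had 34.1 and 178, and Ctss, a lysosomal protease, 29.2 and 165. Without U1 and U2 the list median was -0.71, and the log2 ratios of Cx3cr1 and Ms4a6b turned to 1.56 and 0.30. Over all cells the pan-hematopoietic list (-0.31) and the myeloid list (-0.60) were lower as well, led by Fcer1g (82.5 and 194 CPM) and Ly86 (12.3 and 53.8). Within HC1 these 2 lists lay at -0.18 and -0.09, and within HC2 at 0.30 and -0.39. HC1 and HC2 cells together were 52.3% of G2VInt and 42.2% of G2VLo.

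Over all cells, genes of endothelium and of red cells were higher in G2VInt than in G2VLo. The classes differed in share too: U1 cells were 2.87% and 16.3% of these groups, and HC2 cells 15.8% and 7.63%. All 18 measured pan-endothelial genes had positive ratios (median 0.35, percentile 100), among them Plvap, a component of endothelial fenestrae (930 and 549 CPM), and Ramp2 (678 and 400). All 5 venous genes (median 0.40) and all 8 BMP and TGF-beta genes (0.33) did too. Of 9 erythroid genes, 8 had positive ratios (median 0.55), with 33.5 and 5.63 CPM of Klf1 and 45.6 and 12.98 of Gata1, both transcription factors of the red cell lineage. Within classes the pan-endothelial median was 0.32 in EC cluster 1, 0.15 in EC cluster 2, 0.27 in HC1 and -2.25 in HC2. The erythroid median was -0.94 in EC cluster 1, 0.25 in HC1 and 1.24 in HC2. Transcription factors of the endothelial-to-hematopoietic transition (0.23, 13 of 15 positive) and HSC genes (0.18, 19 of 21 positive, among them Prdm16 with 23.5 and 12.6 CPM) lay slightly above other genes, and the megakaryocyte list had 0.33 with 6 of 8 positive. Counts of positive ratios say little alone here: the median log2 ratio of all genes was 0.18, and 24 of 41 S phase genes were positive. The S phase (-0.15), cholesterol synthesis (-0.19) and housekeeping (-0.27) lists lay slightly below. Immediate-early and heat-shock genes, which cells switch on within minutes of a stimulus, were lower in G2VInt (-0.81, 13 of 14 negative), with 55.0 and 191 CPM of Atf3 and 177 and 439 of Fos. The arterial (0.09), lymphoid (-0.27), Notch (-0.11), interferon (-0.17), G2 and M phase (-0.05), kinase inhibitor (-0.20), glycolysis (-0.10), p53 target (-0.05) and imprinted (0.12) lists lay inside the range of random lists, and the mast cell, mesenchymal, epithelial, neural and germ cell lists had too few measured members for a median here.

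The highest single genes in G2VInt cells were Reln, Col13a1, Cldn11, Emp1, Tmsb10, Stmn2, Ass1, Pnck, Zbtb16 and Nrxn3. Reln, which encodes the secreted protein reelin, had 11.7 CPM against 0.454 (25.7-fold) and was read in 65.6% of G2VInt cells and 1.69% of G2VLo cells. With all reads it was seen in 100% of G2VInt cells, at a median of 17.5 reads in the shallower and 17 in the deeper ones. Col13a1, a collagen that spans the membrane, had 17.0 and 2.66 CPM, the tight junction gene Cldn11 had 28.5 and 4.73, and Tmsb10, an actin-binding thymosin, had 122 and 30.7 with a read in 98.2% and 72.2% of cells. The median log2 ratio of all 10188 measured genes was 0.18, and TMM scaling would move every ratio by -0.14. The G2VInt and G2VLo libraries come from separate blocks of library numbers, so block and gate cannot be told apart in this comparison.

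Within HC1, genes of mitosis were higher in G2VInt cells. Of 52 G2 and M phase genes, 51 had positive ratios in 102 G2VInt against 163 G2VLo cells (median 0.54, percentile 100), among them the kinases Aurka (230 and 89.98 CPM) and Nek2 (73.9 and 25.1) and the ubiquitin-conjugating enzyme Ube2c (416 and 178), while the S phase list lay at -0.22. Immediate-early genes were lower in G2VInt (-1.06, 12 of 13 negative), with Fos at 39.6 against 142 CPM and Btg2 at 37.4 against 152. The arterial (0.28), pan-endothelial (0.27) and megakaryocyte (0.43) lists were higher, HSC genes slightly (0.14; Prdm16 45.7 and 18.8 CPM), and cholesterol synthesis genes lower (-0.33). Besides Reln (12.7 and 0.0664 CPM) and Tmsb10, the highest named genes were Yap1, the effector of Hippo signaling (14.2 and 3.10), Aplnr, the apelin receptor (14.4 and 3.49), and the helicase Pif1 (32.9 and 8.30). The lowest were AU041133, Btg2, Nr4a1 (81.2 and 320), Fos and the cell death gene Bcl2l11 (4.98 and 17.4). HC1 joins clusters 7 and 8, with 63 and 39 of the G2VInt but 71 and 92 of the G2VLo cells. In a comparison added after these values were seen, the G2 and M phase median was 0.57 in cluster 7 and 0.67 in cluster 8, the immediate-early one -1.39 and -1.02, the arterial one 0.04 and -0.41, the pan-endothelial one 0.08 and 0.07 and the HSC one 0.17 and 0.02. Nr4a1 had a log2 ratio of -0.24 in cluster 7 and -2.68 in cluster 8, and Aplnr 0.76 and 2.96. The median shift of all genes was 0.15. The immediate-early median differed by library numbers, -0.43 in the lower and -1.91 in the upper ones.

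HC2 held different cells in both gates. In G2VInt it leaned to red cells, with an erythroid median of 1.24 over 11 genes (Car1 196 and 48.5 CPM), whereas G2VLo HC2 cells had more reads of HSC genes (-1.28, and -3.07 with the upper library numbers; Hoxa9 4.16 and 70.6, Mecom 0.979 and 11.0), of the lymphoid list (-2.50, and -4.01 with these; Flt3 3.54 and 63.4) and of pan-endothelial genes (-2.25). Papss2 (39.5 and 0.536 CPM), Pkd1l2 (10.7 and 0.292) and Krt8 (12.3 and 0.390) were among the highest, with Pcx, for which 1 read was found in G2VLo (0.0487 CPM, interval 0.00123 to 0.271, against 13.5), and Reln, for which 0 reads were (at least 79.9-fold higher in G2VInt, with 3 reads put in place of 0). Fzd9, a Wnt receptor (0.0670 and 21.7), Cd33, Lax1, Tnni2 and Fkbp10 were the lowest. Unlike in HC1, G2 and M phase genes were lower in G2VInt (-0.36, 37 of 52 negative). The myeloid list was also lower in G2VInt HC2 cells (-0.39, 8 of 11 negative). The HC2 sets hold 44 and 36 cells, and 23 of the 36 lie in cluster 9 while 36 of the 44 lie in clusters 10 and 11. The myeloid gene Mpo is among the leading genes of cluster 9.

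The EC clusters differed in other genes. In cluster 1 (68 and 60 cells), the highest were the potassium channel Kcnh1 (12.0 and 0.178 CPM), Agr2 (19.4 and 0.968), the water channel Aqp1 (38.6 and 3.01), Mamld1 and Emp1, and the lowest were the chemokine Cxcl1 (2.06 and 19.04), Itga2b (10.0 and 57.4), Gnaz and Magel2. Itga2b belongs to megakaryocytes and HSCs, and 8 of 10 genes of the megakaryocyte list were at least 2-fold lower in G2VInt (median -4.01, between -5.84 with the lower and -2.36 with the upper library numbers). The reads came from few G2VLo cells: Pf4, a platelet chemokine (2.01 and 107 CPM), was read in 18.3% of them and Plek in 10.0%. Genes of S phase (-0.43) and of G2 and M phase (-0.46) were lower too. In cluster 2 (54 and 124 cells) Reln (16.2 and 1.22), Cldn11 (27.2 and 3.74), Ptpn6, Efnb1 and Emp1 (42.7 and 11.1) were the highest and Pcgf5, Tnfrsf9 (5.21 and 16.0), Msl3l2, Dcbld2 and Hist1h2ae the lowest, immediate-early genes lay at -0.58, and the median of all genes was 0.17.

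The next comparison asks which genes mark the CD27+ cells, and the first set against them is G2VLo. CD27+ libraries form a block of numbers of their own inside the range of G2VLo, so block and gate cannot be told apart. Cd27 had 126 CPM in CD27+ cells (123 to 128) and 28.0 in G2VLo cells, 4.49-fold higher, and was read in 78.2% (69.7 to 85.2) and 29.9% of cells. EC cells, which should lack it, gave a read in 5.43% of G2VLo cells (median depth 644422) and 9.02% of E11.5 G2VInt cells (median depth 2206968). Gata2 was 70.4 CPM (68.6 to 72.3), 1.05 times the level of G2VLo cells. Kit was 407 against 252 CPM, and Pecam1 309 against 498. Of the cells that could be sexed, 14.0% were male among CD27+ and 48.6% among G2VLo cells, so the embryos sampled differed.

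HSC genes and the factors that drive blood out of endothelium were higher in CD27+ cells, while the pan-hematopoietic (-0.23, 10 of 17 negative) and myeloid (-0.30) lists were lower. Of 21 HSC genes, 19 had positive ratios (median 0.66, percentile 100): Hlf, a transcription factor of HSCs, had 76.1 CPM against 22.6, the chromatin protein Hmga2 247 against 85.6, and Ly6a, the antigen Sca-1, 10.5 against 3.26. The 19 include Cd27, on which these cells were sorted. Of 15 transition factors, 14 were positive (0.66), with 63.6 and 13.5 CPM of Gfi1, a repressor that shuts off endothelial genes, 343 and 141 of Lmo2, 138 and 62.5 of Myb and 177 and 93.0 of Runx1. Pan-endothelial genes were lower, all 18 of them (-0.72; Emcn 313 and 825, Robo4 69.2 and 192), and venous genes more so (-1.48; Aplnr 204 and 845). The lymphoid list was higher (0.87; Flt3 39.9 and 18.1, Ltb 41.3 and 17.0) with members in both directions, and the erythroid list (1.26, but 0.50 without the CPM filter and 2.12 without U1 and U2) held hemoglobins that were higher (Hbb-bt 34.7 and 7.00) and Gata1 that was not, with 2 reads in CD27+ cells (0.0260 CPM, interval 0.00315 to 0.0940, against 12.98). BMP genes (-0.40), interferon genes (-0.30) and cholesterol synthesis genes (-0.26) were lower, and S phase (-0.04) and G2 and M phase genes (0.07) lay inside the random range. The megakaryocyte list (0.81) turned to -0.29 without the CPM filter.

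The highest named genes besides Hbb-bt, Gfi1 and Cd27 were the potassium channel Kcna3 (14.4 and 2.99 CPM), Tnip3 (15.0 and 3.13), Pnck, Frat2 (32.4 and 7.16), Postn (29.6 and 7.04), Mmp23 and Jund (24.2 and 6.68). Postn, periostin, belongs to the mesenchymal list, all 8 measured members of which were at least 2-fold higher (2.08). Col1a1 had 43.9 CPM against 3.75, but was read in 6.72% of CD27+ cells and in none of those of cluster 8, while Postn was read in 29.0% of cluster 8. The lowest were Slc37a2 (1.29 and 27.9), Fcrls (15.3 and 207), Cd83, Cx3cr1, Lgmn, C3ar1, Hmox1, Rassf4, Gas7 and Csf1r, the receptor for macrophage colony-stimulating factor (66.5 and 474). All 11 macrophage genes were at least 2-fold lower (-2.55), in step with 3.36% of U1 clusters among CD27+ and 16.3% among G2VLo cells. Without U1 and U2 the list median was 0.51 and Csf1r (0.91), Cx3cr1 (2.47), Cd83 (1.00), C3ar1 (2.13) and Fcrls (2.60) turned positive on the log2 scale. CD27+ cells were left out by cluster and G2VLo cells by class, so both groups were not reduced alike.

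Inside cluster 8 (69 CD27+ and 123 G2VLo cells), whose cells with a class were 220 HC1 and 29 HC2, the HSC list was still slightly higher (0.20, 12 of 20 positive; Cd93 194 and 126 CPM, Hmga2 247 and 169), with Gfi1 at 66.2 and 34.2 and Lmo2 at 439 and 231, while the transition factors as a list lay inside the random range (0.11). Cd27, the sorted protein's gene, is among the 12. The cell cycle differed: 38 of 41 S phase genes had negative ratios (-0.50; the licensing factor Cdc6 35.5 and 90.6) and 44 of 52 G2 and M phase genes positive ones (0.28; Mki67 311 and 186, Ube2c 414 and 235). Glycolysis (-0.24, 15 of 16 negative) and cholesterol synthesis genes (-0.41, 14 of 17) were lower, and so was the pan-hematopoietic list (-0.21, 13 of 17). Isg20 (11.9 and 1.71), Zfp775, Peg10, the imprinted gene from a retrotransposon (13.02 and 2.79), Mpnd (58.7 and 12.6) and C1qb (31.1 and 1.499) were the highest. C1qb belongs to macrophages, and Cx3cr1 had 12.0 against 1.35. The macrophage list was higher in CD27+ cells (1.89, 3 of 4 measured genes positive). The lowest were Fitm2, Lrp11, Hinfp (3.23 and 13.5), Plac8 (3.37 and 14.0) and Kdm1b. Cd27 was 175 CPM in CD27+, 99.2 in G2VLo and 151 in G2VInt cells.

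Against E11.5 G2VInt cells, the same CD27+ cells had higher levels of HSC genes (0.47, 16 of 22 positive; Hlf 76.1 and 25.1 CPM, Angpt1 159 and 60.7) and transition factors (0.55, 11 of 15; Gfi1 63.6 and 21.9, Lmo2 343 and 186, Runx1 177 and 95.1), and lower levels of pan-endothelial (-1.17, 0 of 18 positive) and venous ones (-1.97). Gata2 was 2.39-fold higher in G2VInt cells, 168 against 70.4 CPM, and Cd27, which is among the 16 HSC genes, 3.42-fold higher in CD27+ cells. The erythroid list was mixed (0.33, 6 of 11 positive): 3 genes, among them Hbb-bt, were at least 2-fold higher and 5 at least 2-fold lower, among them the factors Klf1 (0.247 and 33.5 CPM) and Gata1 (0.0260 and 45.6). The highest named genes were Postn (29.6 and 4.92), Setbp1 (33.5 and 7.28), Pawr, Tnip3, Hspb1, Kcna3, Il12a (14.5 and 3.88), Pglyrp1, Hbb-bt and Klrb1c, and the lowest Cldn11 (0.403 and 28.5), Slc37a2, Lama1 (1.69 and 22.02), Fmo1 (2.98 and 37.4), Reln (1.05 and 11.7), Bace2, Tll1, Emp1, Col13a1 and Hmox1 (44.8 and 377). Mesenchymal (2.77; 1.65 with the lower and 3.98 with the upper library numbers), lymphoid (1.16, 3 of 5 positive with 2 at least 2-fold lower), myeloid (0.41, 6 of 10) and immediate-early (0.58, 9 of 16) lists had higher medians and BMP (-0.58; Acvrl1 26.2 and 138) and imprinted (-0.32) lists lower. The macrophage list (-0.65) turned to 0.0305 with cells weighted alike and to 1.34 without U1 and U2. The median of all genes was -0.16, and these groups come from separate library blocks.

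Within cluster 8, with 69 CD27+ and 37 G2VInt cells, the HSC list lay inside the random range (0.13), G2 and M phase (-0.34) and S phase genes (-0.26) were lower, and Gata2 was 84.6 CPM in CD27+ and 132 in G2VInt cells. The macrophage list was higher in CD27+ cells (1.51, 4 of 4 measured genes positive). The highest genes were C1qb, Mmp23 (13.4 and 0.715 CPM), Arhgef28, Isg20 and Kctd12b, and the lowest Reln (0 reads and 11.2 CPM, at least 160-fold lower with 3 reads put in place of 0), Clec1a, Zfp324, Hinfp and Evc. The median of all genes was -0.21, and the immediate-early median (0.79) was -0.41 in the lower and 1.55 in the upper library numbers.

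**Figure D3:**
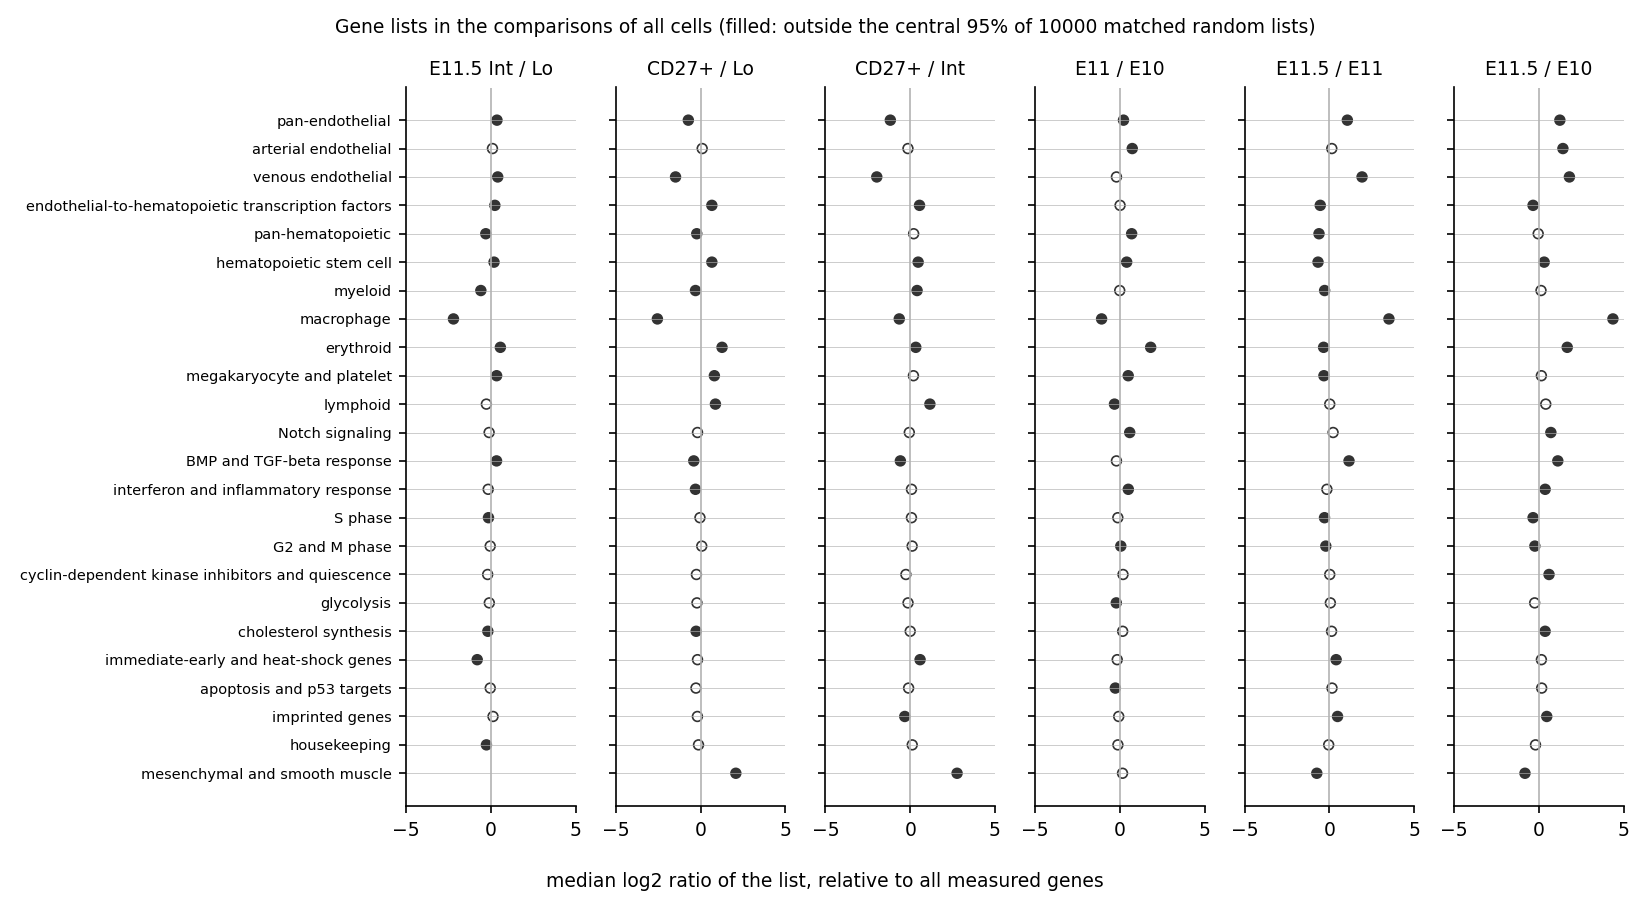
Median log2 ratio of each gene list relative to all measured genes (x axis) for each list (y axis) in the 6 comparisons of all cells; filled points lie outside the central 95% of 10000 matched random lists. The macrophage list goes from -2.55 (CD27+ over G2VLo) to 4.36 (E11.5 over E10), and the HSC list is 0.66 in CD27+ over G2VLo cells.

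The last comparison follows G2VInt cells from E10 through E11 to E11.5, the days on which HSC activity appears in the AGM. The library numbers of E10 and E11 form adjacent blocks that do not overlap, so day and block cannot be told apart. Of the cells that could be sexed, 25.3% were male at E10 and 79.0% at E11, so different mixes of embryos were sampled. Gata2 was 127 CPM at E10 (126 to 129), 237 at E11 (235 to 239) and 168 at E11.5, Cd27 30.4, 60.1 and 36.7, Kit 545, 612 and 342 and Pecam1 385, 443 and 642. From E10 to E11 the erythroid list was higher in all 9 genes (1.82; Klf1 9.25 and 51.1, Gata1 15.4 and 68.7), though 0.87 in the lower library numbers. HC2, which had 277 CPM of Gata1 at E11 against 3.27 in HC1, was a larger share of the cells at E11, and within HC1 the erythroid median was 0.73 and the pan-hematopoietic one 0.16. The pan-hematopoietic (0.70, 14 of 17 positive), arterial (0.73, 10 of 11), Notch (0.58, 7 of 9), interferon (0.50; Ifitm1 133 and 512) and HSC lists (0.41, 16 of 22) were higher too, and Procr, the protein C receptor found on HSCs, had 63.8 and 247 CPM. Glycolysis genes (-0.21, 15 of 16 negative) and p53 targets (-0.26) were lower. The highest named genes at E11 were Hdc, which makes histamine (1.22 and 146), Tbxas1, thromboxane synthase (0.427 and 14.6), Akr1c14 (1.34 and 31.3), Gpr183, Clec4e, Ly6a (0.861 and 12.3), Arhgap15, Chad, Tfr2 (9.64 and 92.7) and Dpp4. The lowest were Sall3 (14.9 and 1.62) and Sall4 (29.8 and 4.38), factors of embryonic cells, Bcat1, an enzyme of branched amino acids (54.3 and 6.89), Lyve1, Pdgfa, Gpr4, Scamp5, Bex2, Slc24a3 and Fndc3c1.

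HC1 cells had an arterial and HSC program that was lower at E10 than at E11 (63 and 77 cells). The arterial list had a median of 1.47 (10 of 11 positive, 9 at least 2-fold; 2.11 with the lower library numbers), with the kinase Bmx at 2.93 and 34.7 CPM, the gap junction gene Gja5 at 25.2 and 125 and Nrp1 at 31.8 and 158. Notch genes followed (0.84; Dll4 22.7 and 63.8, Hes1 14.7 and 44.3), as did pan-endothelial genes (0.81, 17 of 18 positive; Robo4 5.14 and 57.9). Dll4 is in the arterial list too. Of 21 HSC genes, 18 were positive and 9 at least 2-fold higher at E11 (0.70): Procr had 72.5 and 367 CPM, Mecom 86.2 and 266, Mllt3 38.4 and 149, Ly6a 1.12 and 19.1, Sult1a1 4.47 and 44.9 and Cd27 40.8 and 90.8. Gata2 was 142 and 217. Genes of glycolysis were lower in 15 of 16 cases (-0.39; Slc2a3 148 and 55.5, Eno1 402 and 199) and so were p53 targets (-0.56; Cdkn1a 24.1 and 9.74, Pmaip1 24.1 and 5.95). Cluster 7 held 27 of the HC1 cells at E10 and 46 at E11, cluster 8 held 36 and 31, and Bmx, Akr1c14 and Sult1a1 are among the leading genes of cluster 7. In a comparison of each cluster alone, added after these values were seen, the arterial median was 1.66 in cluster 7 and 1.39 in cluster 8, and the HSC median 0.56 and 0.87. The highest named genes were Slc40a1, the iron exporter (1 read or 0.00757 CPM, interval 0.000192 to 0.0422, against 12.9), Scrn1 (0.257 and 19.2), Tbxas1 (0.424 and 21.1), Zfp618 and Akr1c14 (1.78 and 49.5). The lowest were Sall3 (12.9, against 3 reads or 0.0153 CPM, interval 0.00316 to 0.0448), Rab44 (11.9 and 0.251), Perp (49.4 and 3.22), Sall4 (34.9 and 3.39) and Ak4 (14.4 and 1.70).

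**Figure D4:**
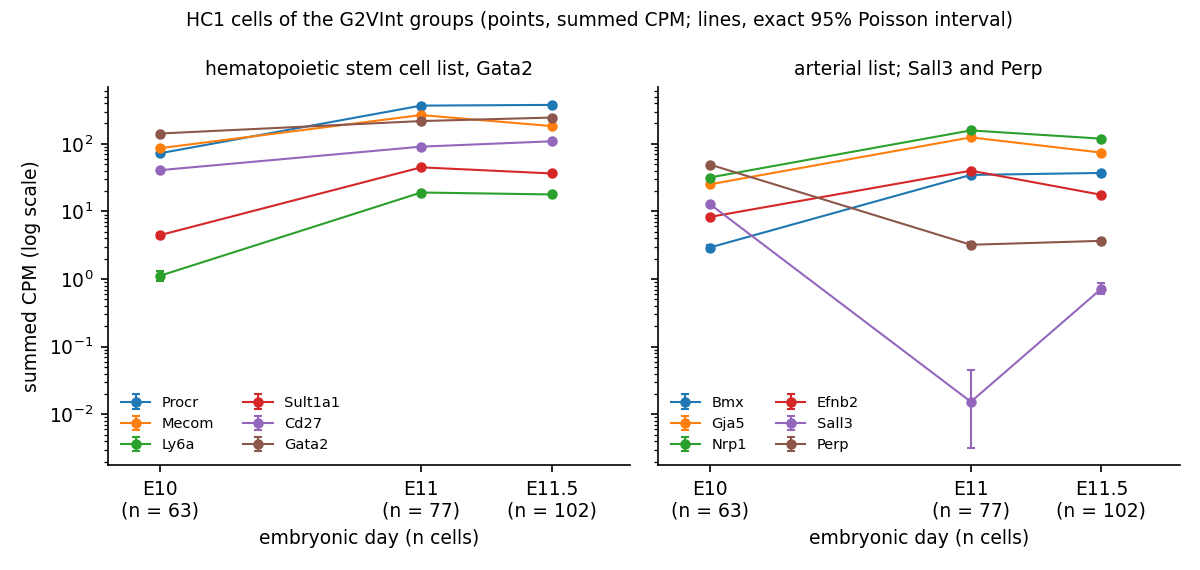
Summed CPM (y axis, log scale) in HC1 cells of the G2VInt groups by embryonic day (x axis, with the number of cells); points are CPM, lines through points join the days of a gene and vertical lines are exact 95% Poisson intervals. Procr goes from 72.5 at E10 to 367 at E11 and 376 at E11.5, and Perp from 49.4 to 3.22 and 3.68.

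Between E11 and E11.5 the share of EC cells differed, and with it the genes. Pan-endothelial genes were higher at E11.5 in 18 of 18 cases (1.06; Robo4 75.2 and 236), venous genes in 5 of 5 (1.93; Aplnr 294 and 1260, the venous factor Nr2f2 16.1 and 57.3) and BMP genes in 7 of 8 (1.16; Bmp4 12.0 and 73.0). Macrophage genes (3.51, 10 of 10; 4.67 with the upper library numbers) were higher where 8 U1 cells were found, with C1qb at 0.0287 and 187 CPM. HSC (-0.67, 20 of 22 negative), pan-hematopoietic (-0.61) and transition genes (-0.54; Runx1 236 and 95.1) were lower. The highest named genes were Reln, Oit3 (2.01 and 33.0), Lyve1 (4.67 and 63.4), Hmox1 (29.3 and 377, a log2 ratio of 1.30 without U1 and U2), Rnase4 (3.16 and 36.5), Fam167b, Ccn2, Rgs16, Slc37a2 and the fatty acid receptor Cd36 (6.17 and 50.5), and the lowest Il12a (17.5 and 3.88), Vipr1, Ephb6, Hdc (146 and 42.0), Clec4e, Tnfrsf26, Stk26, Wdr31 and Eno3. Within HC1 (77 and 102 cells) the HSC list lay inside the random range (-0.10), with Procr at 367 and 376 CPM and Mecom at 266 and 183. The arterial list was slightly lower (-0.28; Efnb2 40.1 and 17.6, Gja5 125 and 74.1), as was that of G2 and M phase (-0.26), but in cluster 7 alone these were -0.44 and -0.50 and in cluster 8 alone 0.12 and 0.03. The lymphoid list was higher (0.56; Ltb 17.8 and 38.4, Flt3 22.3 and 36.0). Reln (3 reads or 0.0153 CPM, interval 0.00316 to 0.0448, against 12.7), Aplnr (1.04 and 14.4), Hspa1a (28.1 and 142), Smurf1 (6.02 and 25.1) and Bex2 were the highest and Spata1, Zfp583, Vangl1 (31.2 and 7.94), Magi3 and Xylb the lowest. The median of all genes was -0.14 over all cells, and day and library block cannot be told apart between E11 and E11.5.

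Against the same E10 cells, HC1 cells of E11.5 also differed in arterial and HSC genes: arterial genes were higher in 11 of 11 cases (1.15), Notch genes in 7 of 8 (1.14, but 0.60 in cluster 7, 0.42 in cluster 8 and 0.53 with the lower library numbers) and HSC genes in 18 of 21 (0.55), with Procr at 72.5 and 376 CPM and Ly6a at 1.12 and 17.8. Tbxas1 (0.424 and 23.7), Chil5, Akr1c14 and Cavin2 were the highest with Reln (2 reads or 0.0151 CPM, interval 0.00183 to 0.0547, against 12.7), and Lyve1 (19.8 and 0.763), Sall3, Perp, Ubash3a (37.1 and 3.01) and Pmaip1 the lowest. Over all cells, Nav3 (0.461 and 12.7), Slc40a1 (2.80 and 75.8), Madcam1, an adhesion protein of vessels (3.56 and 74.5), Rnase4, Rgs16, Gpr183, Cavin2, Tgfbi and Foxc2 followed Reln as the highest, and Bcat1 (54.3 and 4.81), Sall4, Sall3, Tuba8, Plek (223 and 44.2), Sfrp2, Itgb3, Cd200r1, Snhg11 and Prtg were the lowest. All 41 S phase genes had negative ratios (-0.35). These days also come from separate library blocks.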

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

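The minimum of 300000 reads per cell and the tests of HC1 cells by cluster were chosen only after the data were seen. TMM scaling and DESeq2 size factors shift all genes of a comparison alike, by at most 0.159 on the log2 scale, and leave relative medians as they are by construction, and a minimum of 100000 reads left out no cell, so these say nothing about stability. Over all alternatives 253 of 2802 values of gene ratios moved by more than 1.5-fold and 7 reversed. Of 3548 values of list medians, 66 moved and 14 reversed. These totals overstate stability, because TMM, DESeq2 and the minimum of 100000 reads each add 269 ratios and 339 medians to them. Leaving out the CPM filter adds another 269 ratios, which it cannot change. Some changes of sign were not counted as reversals, such as the arterial median in HC1 of E11.5 over E11 (-0.28, but 0.12 in cluster 8). The lower library numbers alone moved 92 of the 269 ratios and the upper ones 71, and 0 reversed. Reversals were made less likely there for genes named by size. These had to keep their direction with either group reduced alone, whereas here both groups were reduced at once. The reversals, and the moves of the larger list medians and of shares of classes, Gata2 and Cd27, are listed below, and the cause was not tested except where leaving out classes shows it. Shares of cells with a read depend on depth by construction. List medians had no value for lack of measured members in 6 of 339 cases with the lower and 2 with the upper library numbers, 5 without U1 and U2 (among them macrophage genes of E11.5 against E11 and E10) and 2 without the deepest cells.

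U1 and U2 were left out together, by class or, for CD27+ cells, by cluster. In CD27+ over G2VLo cells C3ar1 (2.13), Cd83 (1.00), Csf1r (0.91), Cx3cr1 (2.47), Fcrls (2.60) and the macrophage list (0.51) reversed, and the erythroid list was 2.12. In G2VInt over G2VLo cells Cx3cr1 (1.56) and Ms4a6b (0.30) reversed and the macrophage list was -0.71. The macrophage list reversed in CD27+ over G2VInt (1.34) and the mesenchymal list in E11.5 over E10 (0.48, against -0.83). With the mean of per-cell CPM the macrophage list of CD27+ over G2VInt reversed (0.0305), and in cluster 8 it was 0.90 (1.51 as reported).

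Without the CPM filter, genes near 0 entered the lists. Reversals were the macrophage list in E11 over E10 (0.23), also within HC1 (0.43), and in E11.5 over E10 within HC1 (2.88, against -1.14), the megakaryocyte list in CD27+ over G2VLo (-0.29), and, in G2VInt over G2VLo, the erythroid list of EC cluster 1 (0.0671, against -0.94) and the imprinted list of HC2 (0.17, against -1.67). The erythroid list was 0.50 in CD27+ over G2VLo, the mesenchymal list 3.597 in CD27+ over G2VInt, and in cluster 8 of the latter macrophage genes were 2.16 and kinase inhibitors 0.20.

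With the lower library numbers, immediate-early genes in cluster 8 of CD27+ over G2VInt reversed (-0.41), where kinase inhibitors were 0.25 and mesenchymal genes of all cells 1.65. Erythroid genes were 0.87 in E11 over E10, 1.05 in E11.5 over E10, 1.84 in HC1 of the latter and -1.66 in EC cluster 1. Arterial genes in HC1 of E11 over E10 were 2.11, and Notch genes in HC1 of E11.5 over E10 0.53. In E11.5 over E10 macrophage genes were 7.59 and mesenchymal ones -1.44. In G2VInt over G2VLo immediate-early genes of HC1 were -0.43 and megakaryocyte genes of EC cluster 1 -5.84. EC was 48.3% and HC1 25.4% of G2VLo, HC1 was 29.3% of E11.5 G2VInt, and Cd27 was read in 29.5% of E10 and 23.3% of G2VLo cells.

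With the upper library numbers, mesenchymal genes of E11.5 over E10 (1.07) and imprinted genes in HC2 of G2VInt over G2VLo (0.92) reversed. In the latter comparison HSC genes of HC2 were -3.07 and lymphoid ones -4.01, immediate-early genes of HC1 -1.91, and in EC cluster 1 erythroid genes were -3.31 and megakaryocyte genes -2.36. Erythroid genes of E11.5 over E10 were 2.75, macrophage genes of E11.5 over E11 4.67 and those in HC1 of E11 over E10 -0.37. In cluster 8 macrophage genes were 2.59 against G2VLo and 2.70 against G2VInt, where immediate-early genes were 1.55, and mesenchymal genes of CD27+ over all G2VInt cells were 3.98. EC was 29.7% and HC1 43.6% of G2VLo, HC1 was 43.9% of E11.5 G2VInt, Cd27 was read in 53.5% of E10 and 36.4% of G2VLo cells and Gata2 in 97.7% of E10 cells.

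Without the deepest 5% of cells, macrophage genes in HC1 of E11 over E10 were -0.47 and megakaryocyte genes of EC cluster 1 -5.48. In HC1 cells of cluster 7 alone, macrophage genes were -0.31 in E11 over E10 and reversed in E11.5 over E10 (0.48). In those of cluster 8 alone, erythroid genes were 1.36 and 1.47 in these comparisons and Notch genes 0.42 in the latter. With at least 300000 reads HC1 was 30.1% of G2VLo. By the clustering of all cells HC2 was 4.03% of G2VLo, and U2 was 0% at E10, 0% at E11, 0% in E11.5 G2VInt and 1.06% in G2VLo. Each cluster was given its main class there. Cluster 4, with 16 EC and 11 U2 cells, counted as EC, and cluster 8, with 29 HC2 cells, as HC1. These lower shares therefore follow from the mapping and say little about stability.

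Counting cells with at least 5 reads, Cd27 was found in 21.8% (E10), 30.0% (E11), 20.8% (E11.5 G2VInt), 19.7% (G2VLo) and 63.0% (CD27+) of cells and Gata2 in 74.7%, 81.5%, 75.3%, 47.0% and 50.4%. Without thinning Cd27 was read in 67.8% (E10), 69.2% (E11), 63.1% (E11.5 G2VInt) and 38.1% (G2VLo) and Gata2 in 98.5% (E11), 98.9% (E11.5 G2VInt) and 75.9% (G2VLo). At 50000 reads Gata2 was read in 80.5% (E10), 86.7% (E11.5 G2VInt), 60.2% (G2VLo) and 68.9% (CD27+).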

Other observations

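All 3 tests of Reln, both tests of the immediate-early genes and the test of class mixture for Gata2 were chosen only after the results were seen, and the Gata2 test in a common range of depth after the first depth test; that library numbers must agree for the shared range to be judged was also set after they were seen.

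Some sorted cells carried little of the genes they were sorted on. Of the 77 U1 cells of G2VLo, 6 had a read of Kit at equal depth (7.79%, interval 2.91 to 16.2) and 3 a read of Gata2 (3.90%, 0.811 to 11.0), while Csf1r was read in 77 of 77 at 2974 CPM. The complement gene C1qb had 4815 CPM in these cells and 5675 in the 8 U1 cells of E11.5 G2VInt. In CD27+ cells the embryonic hemoglobin Hba-x (51.8 CPM) was read in 3.36% of cells and Col1a1 (43.9 CPM) in 6.72%, and cluster 8 cells had 0.140 and 0.0467 CPM of them.

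The mix of male and female cells differed between groups. Among cells with reads of either Y-linked genes or Xist alone, the Y-linked ones made up 25.3% at E10 (16.4 to 36.0), 79.0% at E11 (70.6 to 85.9), 49.3% in E11.5 G2VInt (43.2 to 55.3), 48.6% in G2VLo (43.8 to 53.3) and 14.0% in CD27+ cells (8.24 to 21.8).

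Gata2 was 2.51-fold higher in G2VInt than in G2VLo cells, as the reporter gates would give. A different mixture of classes was argued against as the whole cause, since the ratio was at least 1.48 within each of EC clusters 1 and 2, HC1 and HC2 with either group reduced to its lower or upper library numbers. It can still add to the 2.51-fold gap. U1 cells, 16.3% of G2VLo and 2.87% of G2VInt, had 0.273 and 17.8 CPM of Gata2. Depth stayed open: the shallower G2VInt HC1 cells had 0.751 times the Gata2 CPM of the deeper ones (199 and 265), and HC1 cells of 600000 to 1500000 reads gave a ratio of 1.49 (190 and 127 CPM, 48 and 38 cells) while their median depths still differed (1034762 and 696411). The library blocks cannot be told apart from the gates, as 0 G2VInt cells had library numbers among those of G2VLo. The reporter gate remains a candidate explanation beside depth and block.

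Reln was read in the EC, HC1 and HC2 cells of E11.5 G2VInt, the highest of these levels being 1.11 times the lowest, which argues against expression by 1 class, although EC clusters 1 and 2 differed (7.49 and 16.2 CPM) and U1 cells had 5.99 CPM. Day or reporter level alone was argued against too, because HC1 cells of G2VLo and of E11 had at most 0.524% of its level. Shallower and deeper libraries held nearly the same number of Reln reads (medians of 17.5 and 17, ratio 0.971) at a 2.01-fold difference in depth, as a fixed number of reads added to each library of this block would give. Such an addition may be the source of the Reln reads, although the lower library numbers had a median of 13 reads and the upper ones 21.

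Immediate-early and heat-shock genes were lower in G2VInt than in G2VLo cells within each class compared, with the median nearest 0 at -0.47 (EC cluster 1), which argues against a mixture of classes. Handling of the range of libraries that holds G2VLo and CD27+ cells could give the same pattern, and in cluster 8 the list was higher in CD27+ than in G2VInt cells (0.79) and near its level in G2VLo cells (-0.12 for CD27+ over G2VLo). The lower and upper library numbers disagreed for CD27+ over G2VInt (-0.41 and 1.55), so handling and reporter level cannot be told apart. Mitochondrial genes took a median of 2.93% of the reads in G2VInt and 6.41% in G2VLo cells, so cell condition stays open as well. A biological response of the cells to low Gata2 was not tested.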
